A study of Mus musculus with 8 samples.

How the data were processed

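Polyadenylated mRNA from the hearts of mice carrying a Carns transgene (TG) and of wild-type mice (WT) was sequenced, with 4 samples per group, and RNA isolation and library preparation took place at the Beijing Genomics Institute, per the labels' protocols. Each sample has a title with its group and a replicate number, and the groups were taken from those titles. The labels do not say whether the 4 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

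Each deposited table lists genes by NCBI Gene number with an expected count and an FPKM value, per the file headers. The expected count is an estimated number of reads or fragments per gene, as deposited by the authors, and it was not normalized. About 79.2% of the expected counts of TG replicate 1 were whole numbers to the decimals given, and the share in the other libraries lay between 79.0% and 79.8%. The deposited FPKM values are the authors' estimates per kilobase of gene and per 1000000 fragments. Bowtie2 and the mouse build mm8 are named in the submitters' processing notes, without a role or a version. The program that made the counts is not given in the sources used here, nor is the use of strand. Genes with a value of 0 are not listed in a library's table, and such genes were taken as 0 in that library.

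The tables held 18215 gene numbers over the 8 libraries, and 18174 of them were matched by number to a symbol in the NCBI gene table of mouse assembly GRCm38.p6. That assembly differs from the build in the submitters' notes, so it was used for names only and no coordinates are given. No mitochondrially encoded mRNA was listed, and that list was not analysed here. Counts of near-identical genes, such as Acot1 and Acot2, the globin genes and ribosomal protein genes with processed copies, depend on how shared reads were divided and are uncertain.

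Expected counts were rounded to whole numbers. Library totals lay between 6261193 and 7897629 counts, and 3 counts in a library correspond to 0.380 to 0.479 counts per 1000000 (CPM). This floor covers counting error only, since reads without molecular identifiers are not independent molecules. Genes were kept with edgeR's filterByExpr for the groups (minimum count 10, minimum total 15), which left 12670 genes. The main comparison was edgeR's quasi-likelihood F-test (version 4.0.16, in R 4.3.3) with TMM scaling and the design of group alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values in the text use the TMM-scaled library sizes, and fold changes are TG relative to WT. The standard error (SE) given with them is the absolute log2 fold change divided by the square root of the F statistic. Log-scale library values used a prior count of 2.

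Lists of genes, 24 of pathways and 18 of cell type markers, were fixed before the data were examined, together with the design, the rule for naming genes and most of the other settings tried. The 36 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The remaining 6 lists, with fewer tested members, were not analysed here as lists. Members were also adjusted over the list alone. Named genes were Carns1, then the 12 genes with the largest fold change in each direction among those past the threshold, separated between groups, at a mean of at least 1 FPKM in a group and with a symbol that is not a placeholder. Fewer than 5 genes passed in each direction, so the rule took the 5 with the smallest unadjusted p in that direction, stated as not past the threshold where that holds. It added up to 4 members of any list with the smallest unadjusted p and the most abundant member. Some genes that the rule takes are not reported here. Cndp2 and the genes named for the depth of the libraries, or for tissue in TG replicate 2, were chosen after their values were seen.

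The scripts were tested on simulated counts drawn from the means and sizes of these libraries for TG against WT, with 12547 genes and 200 changed genes in each of 5 runs. The edgeR test recovered 30.7% of 1.5-fold, 75.2% of 2-fold and 96.4% of 4-fold changes, and 40 of 713 calls were false. A list of 30 genes raised by 0.3 on the log2 scale had an unadjusted camera p under 0.05 in 5 of 5 runs. An unchanged list had one in 0 of 5. The real lists were called at a p adjusted over 36 lists, which is stricter. Genes were drawn independently of each other in these runs. In the real libraries the estimated inter-gene correlation of the lists lay between -0.08 (ketone body) and 0.83 (erythroid). The runs therefore cannot show how often the list test makes false calls here.

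The smallest chi-square per degree of freedom between 2 libraries of a group was 4.51, over 12599 genes, so no pair agreed within sampling noise. Transcripts of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in every library, at 5.57 CPM or more, and Xist was at most 1.43 CPM. A fit with sex as a covariate therefore had nothing to adjust and was not run.

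The other settings fixed in advance were DESeq2 1.42.0, RLE and upper-quartile scaling, no low-count filter, a mean of at least 5 CPM, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) for genes at a mean of at least 0.5 FPKM, limma voom with library weights, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Added after seeing the data were the depth class of the libraries as a covariate, offsets for GC content and gene length fitted with splines of 5 degrees of freedom, each depth class alone, the counts without Carns1, and 2 lists without named members. GC content was taken from the transcripts of the reference annotation and was known for 12264 of the tested genes (96.8%). Figures were drawn with matplotlib 3.10.9.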

Results

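The transcriptomes of mouse hearts with and without a Carns transgene were compared. Carns1 encodes carnosine synthase, which joins histidine to beta-alanine or gamma-aminobutyrate to form histidyl dipeptides such as carnosine. The question was which heart transcripts differ when this gene is overexpressed. Each group held 4 libraries. The total expected counts lay between 6261193 and 7897629 in TG and between 6277698 and 7778422 in WT, and 15877 to 16109 genes were listed per library.

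Carns1 (NCBI Gene 107239) was far more abundant in every TG library than in any WT library. It stood at 20812 ± 2454 CPM in TG and 62.6 ± 12.5 CPM in WT (SD, n = 4 each), a 332-fold difference. The log2 fold change was 8.38 (SE 0.21, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.07e-10). Carns1 took 1.92% to 2.36% of all counts in the TG libraries and 0.005% to 0.007% in the WT libraries. The labels do not give the sequence the transgene carries, so the counts cover reads assigned to mouse Carns1.

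Beside Carns1, Lrrc15 passed the threshold. Lrrc15 (NCBI Gene 74488), a leucine-rich repeat membrane protein known from fibroblasts, fell from 24.3 ± 4.8 CPM in WT to 9.74 ± 1.67 CPM in TG (SD, n = 4 each), and its 4 TG values lay below its 4 WT values. Its log2 fold change was -1.32 (SE 0.18, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.035). In all, 2 of 12670 genes changed, 1 higher and 1 lower in TG, while 442 had an unadjusted p under 0.05 (194 higher, 248 lower). Chance alone gives a share of 0.05 of the genes, which is more than these 442. The share depended on the fit. With the depth class as a covariate, a fit chosen after the data were seen, 1136 of 12670 genes had such a p. That is above a share of 0.05. DESeq2 called 15 genes. In 320 genes (2.53%) the groups did not overlap, where chance gives 2.86%. The Lrrc15 call was lost without any one of TG replicates 1, 2 and 4 or WT replicates 1, 2 and 3, with edgeR Benjamini-Hochberg adjusted p values of 0.124, 0.134, 0.189, 0.123, 0.182 and 0.066. The log2 fold change of Lrrc15 lay between -1.39 and -1.22 in those fits. The call was also lost with limma on log2(FPKM + 1) and on log2(FPKM + 0.1) (adjusted p = 0.121 and 0.103) and with the replicate number as a block (0.055), at log2 fold changes of -0.97, -1.28 and -1.31. With the Carns1 reads left out, a fit chosen after the data were seen, the adjusted p of Lrrc15 was 0.070 (edgeR, Benjamini-Hochberg). Its log2 fold change there was -1.32, so the call in the main fit depends on Carns1 being adjusted with it.

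The genes with the next smallest p in each direction, 5 higher and 4 lower, did not pass the threshold in this fit, while DESeq2 called all 9 of them (Benjamini-Hochberg adjusted p between 1.63e-04 for Fam81a and 0.026 for Cxcl9). On the higher side in TG stood Fam81a (19.0 ± 3.6 against 8.53 ± 1.58 CPM), Sort1, the sorting receptor sortilin (88.2 ± 11.1 against 56.2 ± 4.5 CPM), the interferon-induced chemokine Cxcl9 (12.5 ± 1.7 against 6.86 ± 0.69 CPM), the hyaluronidase Hyal1 (11.5 ± 2.0 against 5.70 ± 1.22 CPM) and Tmem130 (1.96 ± 0.59 against 0.14 ± 0.16 CPM; SD, n = 4 each). On the lower side stood the cadherin Cdh22 (0.68 ± 0.18 against 4.10 ± 1.62 CPM), Sh3rf2 (25.4 ± 1.1 against 41.9 ± 4.4 CPM), Ogdhl, which resembles the oxoglutarate dehydrogenase subunit of the tricarboxylic acid cycle (86.7 ± 20.5 against 158 ± 9.2 CPM), and Ptprn (5.71 ± 0.97 against 10.95 ± 0.94 CPM; SD, n = 4 each). In each of these 9 genes the groups did not overlap. Selection by smallest p in the same libraries favours this. Neither it nor the DESeq2 calls on the same counts are therefore separate support for these genes. Their edgeR Benjamini-Hochberg adjusted p values ran from 0.063 for Cdh22 to 0.188 for Hyal1. Tmem130 in WT and Cdh22 in TG lay near the level of 3 counts per library.

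**Figure D1:**
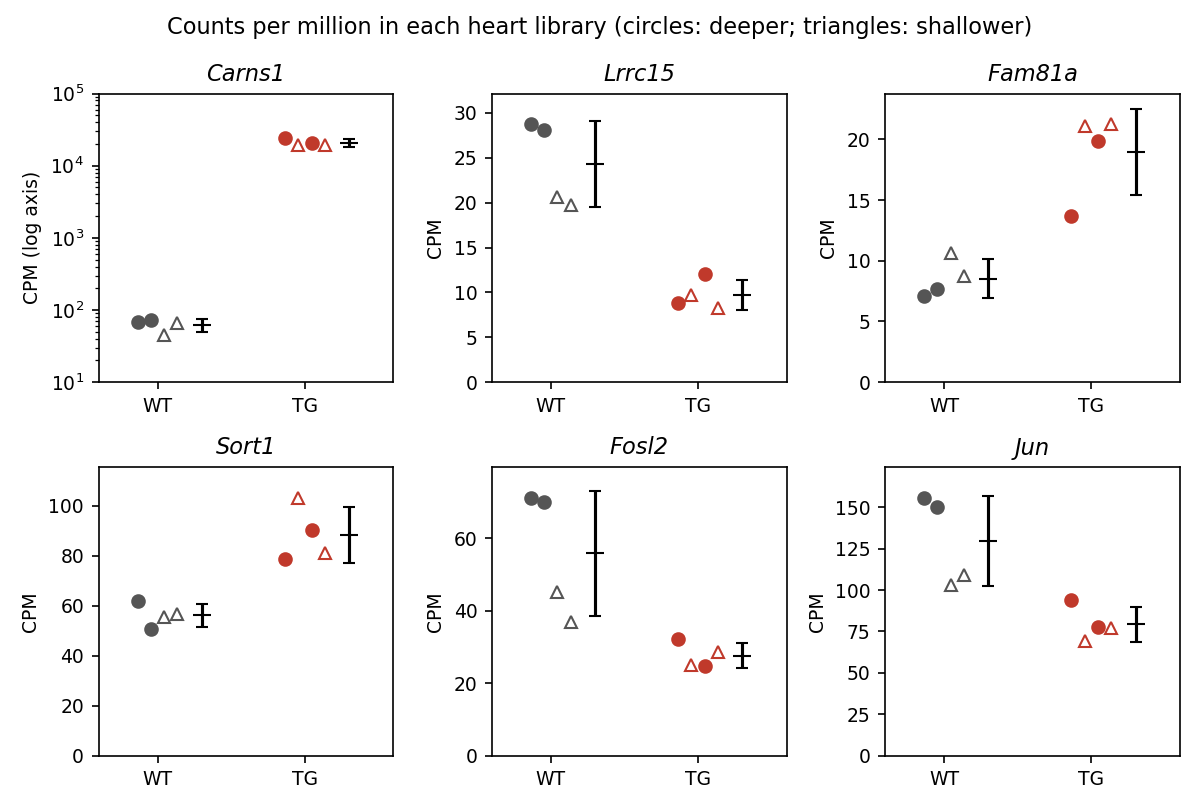
CPM (y axis) of 6 genes in each of the 4 WT (grey) and 4 TG (red) heart libraries, with the mean and SD of each group in black. Carns1 is on a log axis and the others start at 0; circles are the 4 deeper and open triangles the 4 shallower libraries. Carns1 averaged 62.6 CPM in WT and 20812 CPM in TG, and of the others Lrrc15 alone passed the threshold over all genes in the main edgeR fit.

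Of the genes that make, split or carry histidyl dipeptides and their precursors, 13 were tested. Carns1 was the 1 member that passed over all genes and adjusted over the list alone. Abat, which breaks down gamma-aminobutyrate and beta-alanine, stood at 9.91 ± 1.75 CPM in TG and 13.1 ± 2.2 in WT. Csad, which decarboxylates cysteine sulfinate, stood at 7.48 ± 1.37 and 6.04 ± 0.84, and Hdc, histidine decarboxylase, at 2.91 ± 0.43 and 3.82 ± 1.09 (SD, n = 4 each). Cndp2, a cytosolic dipeptidase, stood at 42.1 CPM in TG and 42.7 in WT, a log2 fold change of -0.02 (SE 0.14). The list rose by camera (Benjamini-Hochberg adjusted p = 4.12e-17; adjusted p = 0.0057 with an estimated correlation), with a mean log2 fold change of 0.60 and a median of -0.01, so the median and the test differed in sign. The call was lost with limma on log2(FPKM + 1) and on log2(FPKM + 0.1) and with voom and library weights (camera, Benjamini-Hochberg adjusted p = 0.274, 0.431 and 0.144). The median lay between -0.07 and 0.06 when 1 library was left out, and without Carns1 the adjusted p by camera with Benjamini-Hochberg adjustment was 0.729.

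Immediate early genes, the transcription factors and regulators induced within minutes of a stimulus, were lower in TG as a list. Of 24 tested members 21 had a negative fold change, with a median of -0.27 (camera, Benjamini-Hochberg adjusted p = 1.42e-09; adjusted p = 0.835 with an estimated correlation). The mean log2 level of the list, relative to the mean of all libraries, was 0.51, 0.46, 0.21 and -0.42 in WT replicates 1 to 4 and 0.11, -0.12, -0.55 and -0.20 in TG replicates 1 to 4, so WT replicate 4 stood below 3 of the TG libraries. Fosl2 stood at 27.6 ± 3.5 CPM in TG and 55.8 ± 17.3 in WT, and Jun at 79.4 ± 10.5 and 130 ± 27 (SD, n = 4 each), both subunits of the AP-1 factor. These 2 genes passed when adjusted over the list alone, and none of the list passed over all genes in the main edgeR fit. DESeq2 called both Fosl2 and Jun over all genes (Benjamini-Hochberg adjusted p = 0.0021 and 0.020). The orphan nuclear receptor Nr4a1 varied widely, from 11.8 to 53.8 CPM in TG and from 17.7 to 196 CPM in WT. The zinc finger gene Egr3 stood at 2.51 ± 0.97 and 4.38 ± 1.08 CPM and the abundant Jund at 218 ± 26 and 234 ± 36 CPM (SD, n = 4 each). The median of the list was -0.53 within the deeper and -0.11 within the shallower libraries, where it was not called (camera, Benjamini-Hochberg adjusted p = 0.119).

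Markers of macrophages and dendritic cells and genes of the type I interferon response also fell as lists by camera, and both calls were lost with an estimated correlation (adjusted p = 0.835 for both). Of 18 macrophage and dendritic markers 17 had a negative fold change, with a median of -0.26 (camera, Benjamini-Hochberg adjusted p = 4.05e-05). Csf1r, the receptor for macrophage colony-stimulating factor, stood at 84.8 ± 12.9 CPM in TG and 109 ± 15 in WT, and the complement genes C1qc and C1qb at 108 ± 26 and 118 ± 29 in TG against 139 ± 10 and 149 ± 15 in WT (SD, n = 4 each). Itgax stood at 1.053 ± 0.385 and 1.71 ± 0.50 CPM, and Cd74, which was highest in TG replicate 1 at 505 CPM, at 323 ± 122 and 348 ± 40 (SD, n = 4 each). Of 33 interferon genes 28 had a negative fold change, with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.0039). Among them Gbp3 stood at 4.89 ± 0.46 and 7.21 ± 1.99 CPM, Irf7 at 16.5 ± 2.3 and 20.4 ± 2.4 and Xaf1 at 9.124 ± 1.005 and 11.2 ± 0.6 (SD, n = 4 each). No member of either list passed over all genes or adjusted over the list alone. Without TG replicate 3 camera called neither list (Benjamini-Hochberg adjusted p = 0.052 and 0.066), and without WT replicate 4 it did not call the interferon list (0.153). The macrophage median was -0.39 without TG replicate 1, -0.15 without TG replicate 3 and -0.08 without WT replicate 4, and the interferon median -0.08 and -0.04 without the latter 2 libraries. Within the deeper libraries neither was called (0.236 and 0.400), with medians of -0.18 and -0.07, and within the shallower libraries both were, with medians of -0.32 and -0.23.

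Small downward shifts were called by camera in the ribosomal, respiratory chain and cell cycle lists, and none of the 3 calls was kept with an estimated correlation (adjusted p = 0.835 for each). Of 75 cytosolic ribosomal protein genes 66 had a negative fold change, with a median of -0.12 (camera, Benjamini-Hochberg adjusted p = 8.02e-05). Of 75 nuclear genes of oxidative phosphorylation 63 had one, with a median of -0.07 (adjusted p = 0.0064), and of 27 cell cycle genes 21, with a median of -0.10 (adjusted p = 0.039, both by camera with Benjamini-Hochberg adjustment). Cox7a1, the heart and muscle form of a cytochrome c oxidase subunit, stood at 909 ± 124 CPM in TG and 1249 ± 92 in WT, while the abundant ATP synthase gene Atp5b stood at 5846 ± 511 and 5714 ± 453 (SD, n = 4 each). The ribosomal genes Rps20 and Rps2 stood at 120 ± 5 and 1364 ± 185 CPM in TG and at 142 ± 24 and 1478 ± 253 in WT. In the cell cycle list the D-type cyclin Ccnd2 stood higher in TG, at 171 ± 22 against 130 ± 20 CPM, and the mitotic genes Cenpf and Cdk1 lower, at 4.21 ± 0.62 and 1.41 ± 0.23 against 8.48 ± 4.45 and 2.12 ± 0.11 (SD, n = 4 each). No member of these 3 lists passed over all genes or adjusted over the list alone in the main fit. Without WT replicate 2 the ribosomal and respiratory medians were -0.03 and 0.01 and neither list was called (camera, Benjamini-Hochberg adjusted p = 0.862 for both), without TG replicate 4 neither was called (0.093 and 0.728), and offsets for GC content and length ended both calls (0.248 and 0.731), at medians of -0.04 and 0.01. Within the deeper libraries their medians were -0.18 and -0.12, and within the shallower -0.03 and -0.04, where neither was called (0.453 and 0.212). Without WT replicate 4 these medians were -0.21 and -0.13, without TG replicate 4 -0.07 and -0.02, and the respiratory one was -0.11 without TG replicate 1. The cell cycle call was lost without TG replicate 1 or 2 or WT replicate 3 or 4, with camera Benjamini-Hochberg adjusted p values from 0.053 to 0.131, and its median was -0.16, -0.21 and -0.16 without TG replicate 1, TG replicate 4 and WT replicate 2. That call was also lost with DESeq2, voom with library weights, a mean of at least 5 CPM, the depth class as a covariate and the deeper libraries only (camera, Benjamini-Hochberg adjusted p = 0.073, 0.077, 0.437, 0.110 and 0.388), with medians between -0.12 and -0.08, and in the shallower libraries only it was kept at a median of -0.23.

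The cardiac stress and fetal programme and the adipocyte markers rose as lists by camera, and both calls were lost with an estimated correlation (adjusted p = 0.835 for both). Both lists hold genes that stood far higher in TG replicate 2 than in the other libraries. The atrial myosin light chains Myl7 and Myl4 stood at 203 and 249 CPM in TG replicate 2, at 46.8 and 63.7 in TG replicate 4, and at most 18.8 and 30.01 in the other libraries. Sln, sarcolipin, an atrial regulator of the calcium pump, stood at 79.8 CPM in TG replicate 2 and 14.9 in TG replicate 4. Car3, a carbonic anhydrase abundant in fat and muscle, stood at 393 CPM in TG replicate 2, 18.1 in TG replicate 4 and at most 4.38 in the other libraries. Of 19 stress genes 14 had a positive fold change, with a median of 0.20 (camera, Benjamini-Hochberg adjusted p = 0.022). Outside the atrial genes, Timp1, an inhibitor of matrix metalloproteinases, stood at 4.80 ± 1.65 CPM in TG and 3.14 ± 1.02 in WT, and skeletal actin Acta1 at 678 ± 47 and 590 ± 550 (SD, n = 4 each). The mean log2 level of the list, relative to the mean of all libraries, was 0.90 in TG replicate 2, 0.71 in TG replicate 4 and 0.37 in WT replicate 4, and below 0 in the other 5 libraries. Without TG replicate 2 the median was 0.22 and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.660), and without Myl4, Myl7 and Sln the median was 0.15 (0.119). Leaving out TG replicate 4 or WT replicate 1, 2 or 3 also ended that call, with camera Benjamini-Hochberg adjusted p values from 0.056 to 0.362 and medians of 0.10, 0.11, 0.12 and 0.14, and the median was 0.30 without WT replicate 4. The call was lost as well with a mean of at least 5 CPM, limma on log2(FPKM + 0.1), the depth class as a covariate and GC and length offsets (0.107, 0.071, 0.114 and 0.077, medians between 0.17 and 0.23), and in the deeper libraries only (median -0.01, 0.690).

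Of 5 tested adipocyte markers 4 had a positive fold change, with a median of 0.43 (camera, Benjamini-Hochberg adjusted p = 0.039; adjusted p = 0.835 with an estimated correlation). Car3 passed adjusted over the list alone. The lipase Lipe stood at 106 ± 31 CPM in TG and 78.9 ± 7.1 in WT, the lipid droplet gene Cidea at 41.3 ± 31.6 and 29.9 ± 1.4, and the fatty acid carrier Fabp4 at 440 ± 162 and 442 ± 93 (SD, n = 4 each). Without TG replicate 2 the median was -0.01 and the adjusted p by camera with Benjamini-Hochberg adjustment 0.900, and without WT replicate 1 these were 0.37 and 0.187. Without TG replicate 3 the median was 0.64. The call was also lost with voom and library weights, the depth class as a covariate and GC and length offsets (camera, Benjamini-Hochberg adjusted p = 0.133, 0.181 and 0.077, medians between 0.30 and 0.43), and in the deeper libraries only (median -0.13, 0.805). In the shallower libraries only, which hold TG replicates 2 and 4, 9 members passed the filter and the list was called (3.62e-13), with a median of 6.02 over the 9 and 0.47 over the 5 tested in all 8 libraries.

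Genes of lipid synthesis stood apart in the same library. Scd1, stearoyl-CoA desaturase, stood at 1565 CPM in TG replicate 2 and between 21.4 and 60.9 CPM in the other 7 libraries, and Fasn, fatty acid synthase, at 1004 CPM and between 35.7 and 62.5. The list of lipid and sterol synthesis was not called (28 members, median 0.04, camera with Benjamini-Hochberg adjusted p = 0.142). By the same test it was called without TG replicate 4 (median 0.11, adjusted p = 0.0090) and without TG replicate 3 (0.06, 0.024). The shallower libraries only also gave a call (0.12, 0.0055).

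Among the lists of energy metabolism, none of the fatty acid, ketone body, glycolysis and tricarboxylic acid cycle lists was called by camera (Benjamini-Hochberg adjusted p = 0.220, 0.395, 0.564 and 0.824), with medians between -0.02 and 0.02. By the same test the fatty acid list was called without TG replicate 4 (median 0.06, adjusted p = 0.0034) and without WT replicate 2 (0.04, 0.036). Oxct1, which opens ketone body use, stood at 759 ± 148 CPM in TG and 896 ± 158 in WT (SD, n = 4 each). In the fatty acid list the acyl-CoA thioesterases Acot1 and Acot2 stood at 19.5 ± 6.8 and 111 ± 9 CPM in TG and at 12.9 ± 2.6 and 95.4 ± 4.8 in WT. The carrier Fabp3 stood at 3315 ± 295 and 3551 ± 499 (SD, n = 4 each). In glycolysis Pfkl, the liver-type phosphofructokinase, stood at 209 ± 22 and 167 ± 21 CPM, Pfkfb1 at 7.30 ± 1.49 and 11.3 ± 2.9, and Gapdh at 8818 ± 816 and 8638 ± 669 (SD, n = 4 each). None of these genes passed over all genes in the main fit.

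Carnosine is known to bind reactive aldehydes, and the list of aldehyde and carbonyl detoxification held 35 tested genes. In the main fit none passed over all genes or adjusted over the list alone, and the list was not called (median -0.01, camera with Benjamini-Hochberg adjusted p = 0.850). Aldh1b1, a mitochondrial aldehyde dehydrogenase, stood at 18.9 ± 3.0 CPM in TG and 12.3 ± 4.0 in WT, the glutathione transferase Gstt1 at 16.5 ± 2.1 and 24.0 ± 7.1, and the abundant Gstm1 at 502 ± 69 and 498 ± 61 (SD, n = 4 each). The antioxidant and NRF2 list was not called either (32 genes, median 0.05, camera with Benjamini-Hochberg adjusted p = 0.202), with Taldo1 at 99.6 ± 14.2 and 83.1 ± 8.0 CPM and catalase, Cat, at 332 ± 38 and 283 ± 34 (SD, n = 4 each). By the same test that list was called without WT replicate 2 (median 0.07, adjusted p = 0.011) and without TG replicate 4 (0.06, 0.032).

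No contractile or ion channel gene of the lists passed over all genes in the main fit. Myh6, the main myosin heavy chain of the mouse heart, stood at 27063 ± 3824 CPM in TG and 25646 ± 3737 in WT, Atp2a2, the calcium pump of the sarcoplasmic reticulum, at 10990 ± 277 and 11340 ± 624, and Tnnc1, cardiac troponin C, at 2735 ± 273 and 3296 ± 363 (SD, n = 4 each). The sarcomere, cardiomyocyte and calcium and ion channel lists were not called (camera, Benjamini-Hochberg adjusted p = 0.282, 0.333 and 0.698). The pacemaker channel Hcn4 stood at 10.1 ± 1.0 CPM in TG and 16.9 ± 3.8 in WT (SD, n = 4 each) and passed adjusted over the list of conduction tissue markers alone, a list of 5 tested genes that was not called (adjusted p = 0.368 by camera with Benjamini-Hochberg adjustment). Hcn4 also belongs to the calcium and ion channel list of 36 tested genes, and it did not pass adjusted over that list alone. The potassium channel gene Kcnj5 stood at 69.0 ± 7.3 and 56.1 ± 6.1 CPM, and the sodium channel subunit Scn4b at 108 ± 20 and 80.0 ± 23.0 (SD, n = 4 each). In the deeper libraries only, a fit chosen after the data were seen, Hcn4, Scn4b and skeletal actin Acta1 passed over all genes. Their log2 fold changes there were -0.94, 0.78 and 1.16 (edgeR, Benjamini-Hochberg adjusted p = 0.026, 0.022 and 0.038).

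In the remaining lists no call was made in the main fit. Several were called by camera with Benjamini-Hochberg adjustment in other settings. Among them were extracellular matrix without WT replicate 4 (median 0.18, adjusted p = 2.06e-05), erythroid without TG replicate 4 (-0.48, 4.71e-08) and skeletal muscle without WT replicate 4 (0.50, 0.0011). Atrial markers were called in opposite directions within the deeper (-0.33, 1.41e-07) and the shallower libraries (0.43, 9.18e-10). In the list of unfolded protein response and heat shock (median 0.00, camera with Benjamini-Hochberg adjusted p = 0.985) the chaperones Hsph1 and Hsp90ab1 stood higher in TG, at 88.9 ± 29.7 and 2048 ± 106 CPM against 53.5 ± 9.2 and 1623 ± 159 (SD, n = 4 each). The cochaperone Dnajb1 ranged from 19.99 to 30.1 CPM in TG and from 15.9 to 71.9 in WT. Fibrillar collagen Col1a1 stood at 389 ± 65 CPM in TG and 355 ± 50 in WT, and basement membrane collagen Col4a1 at 872 ± 115 and 913 ± 134. The adjusted p by camera with Benjamini-Hochberg adjustment was 0.161 for extracellular matrix and fibrosis, 0.352 for fibroblast, 0.160 for vascular endothelial and 0.220 for endocardial and lymphatic markers. By the same test it was 0.220 for atrial, 0.161 for Schwann cell and neuron, 0.204 for erythroid, 0.395 for skeletal muscle, 0.635 for epicardial and 0.865 for smooth muscle markers. It was 0.452 for inflammation and chemokines, in which Cxcl9 passed adjusted over the list alone, 0.698 for hypoxia and angiogenesis, 0.792 for the circadian clock, 0.850 for protein degradation and 0.865 for amino acid metabolism, also by camera with Benjamini-Hochberg adjustment. The median and the direction of the test differed in sign for the ketone body, aldehyde, smooth muscle and protein degradation lists, and the mean and the test for the amino acid and unfolded protein lists.

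**Figure D2:**
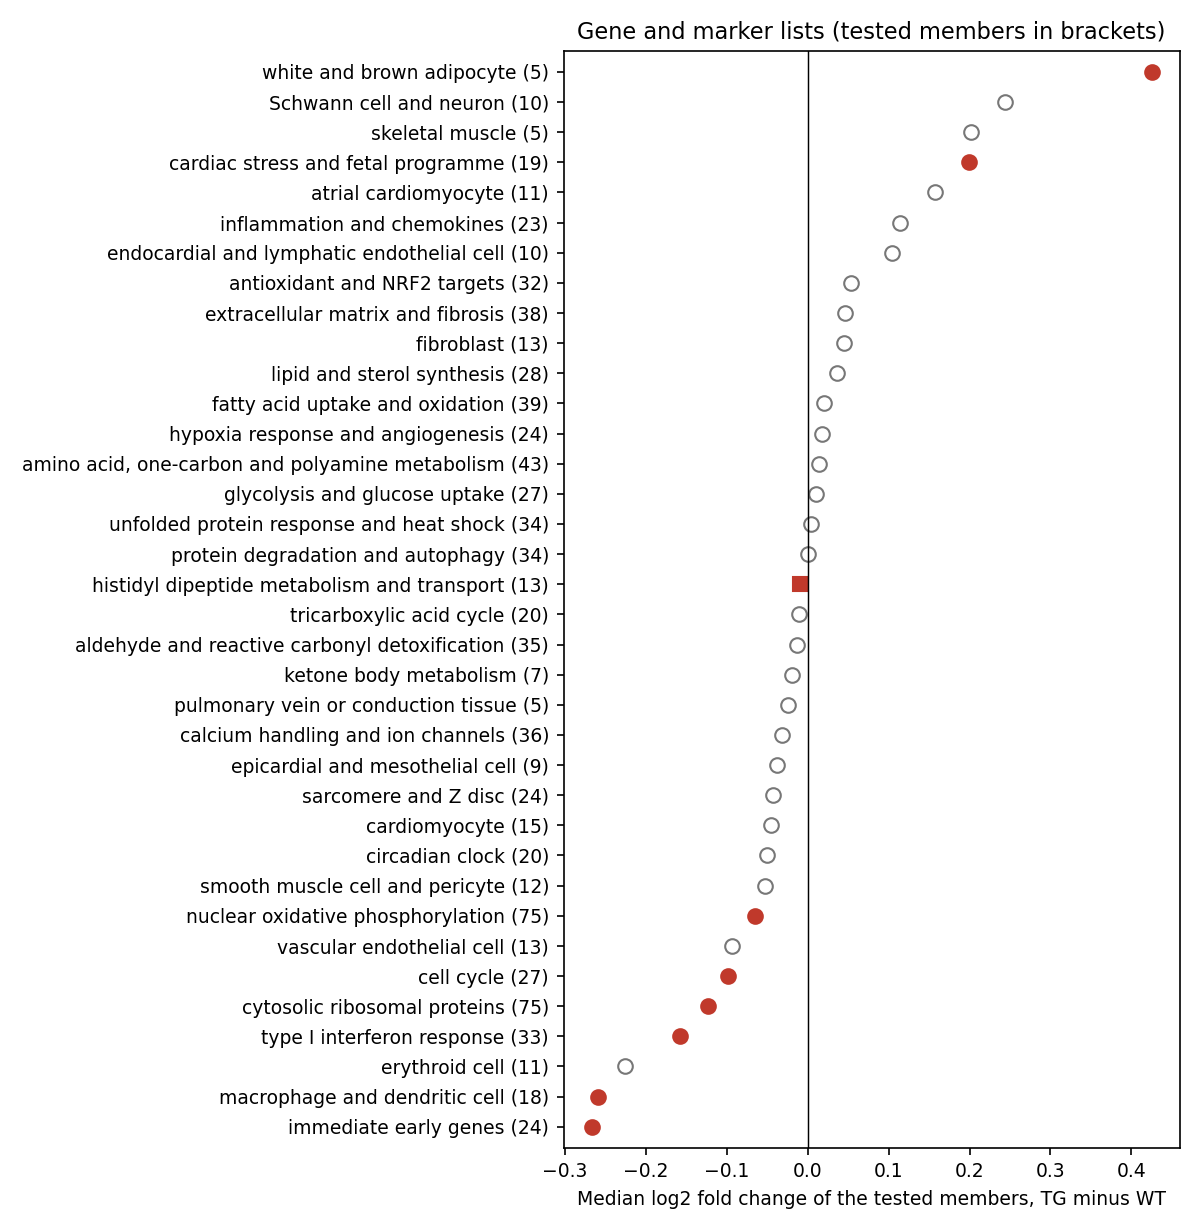
Median log2 fold change (x axis, TG minus WT) of the tested members of each of 36 lists (y axis, number of tested members in brackets). Filled red points are the 9 lists called by camera with a preset correlation and open grey points the others; the square is the histidyl dipeptide list, the 1 call kept with an estimated correlation, whose median is -0.01 because Carns1 alone carries it.

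The libraries also fell into classes that cut across the groups. TG replicates 1 and 3 and WT replicates 1 and 2 had totals of 7394143 to 7897629 counts (deeper), and the other 4 had 6261193 to 6557621 (shallower). The first principal component held 44.8% of the variance, with the deeper libraries between -23.5 and -10.9 and the shallower between 9.48 and 20.9. Between these classes 4078 genes differed by edgeR with Benjamini-Hochberg adjustment, 2256 higher and 1822 lower in the shallower libraries. Across 12264 genes the fold change between the classes had a Spearman rho of -0.69 with GC content, against -0.13 for the fold change between TG and WT, and genes are not independent replicates.

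Within the deeper libraries edgeR called 59 genes between TG and WT (17 higher, 42 lower) and within the shallower 4 (3 higher, 1 lower), with 2 libraries per group in each. With the class as a covariate, a fit chosen after the data were seen, 28 genes passed (10 higher, 18 lower). The log2 fold change of Carns1 was 8.32 (SE 0.13) within the deeper and 8.45 (SE 0.22) within the shallower libraries. That of Lrrc15 was -1.44 (SE 0.17, edgeR with Benjamini-Hochberg adjusted p = 5.12e-04) within the deeper and -1.16 (SE 0.18, adjusted p = 0.168) within the shallower. Camera called 10 lists within the deeper and 12 within the shallower libraries, against 9 over all 8.

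**Figure D3:**
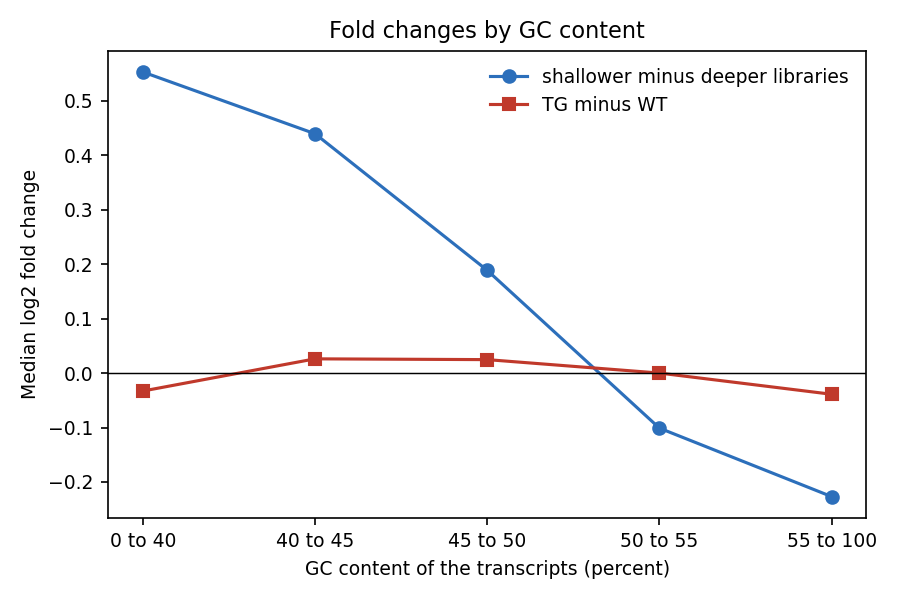
Median log2 fold change (y axis) of genes in 5 bins of transcript GC content (x axis, percent). The blue line is the shallower minus the deeper libraries, from 0.55 in the lowest to -0.23 in the highest bin, and the red line is TG minus WT, which stays between -0.04 and 0.03.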

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

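The tests of explanations in this part were chosen after the results were seen, except those of GC content and of read number for the classes of libraries.

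In a group of 4 a library counts as far from the others when its gap to the nearest, divided by the range, exceeds Dixon's critical value at the 0.05 level, which chance gives in about 5% of groups. Of 260 such tests 25 were positive. Some of the tested genes were chosen after their values were seen, and several belong to the same lists. The 25 positive tests are therefore not independent and cannot be set against that 5%. In TG replicate 2 these were Car3 (393 CPM), Cidea (88.5), Fabp4 (683), Scd1 (1565), Fasn (1004), Acaca (178), Nppa (324), Abat (12.5), Csad (9.52) and Aldh1b1 (23.3), each the highest TG value. The mean log2 level of 2 lists was also highest there, at 0.41 relative to the mean of all libraries for histidyl dipeptides and 0.53 for lipid and sterol synthesis. In TG replicate 1 Cndp2 (53.9 CPM), Cd74 (505) and Mmp9 (54.9) were the highest of their group. In TG replicate 3 Cdh22 was the lowest at 0.42 CPM. In TG replicate 4 Timp1 (7.28 CPM) and Col1a1 (487) were the highest, and Asb14 (55.6) and Irs2 (6.98) the lowest. In the WT group the highest values were Itgax (2.45 CPM) and the Schwann cell and neuron level (0.10) in replicate 1, the antioxidant level (0.082) in replicate 2, Hsp90ab1 (1860 CPM) in replicate 3 and Phyhd1 (61.4 CPM) in replicate 4.

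Markers of tissues beside ventricular muscle also stood high in TG replicate 2. In counts scaled to the plain library totals, Ucp1 of brown fat stood at 124 CPM there against a mean of 0.17 in the other TG libraries, Adipoq at 68.8 against 1.55, Cfd at 169 against 5.80 and Cidec at 83.5 against 2.04. A hypothesis is that this sample may hold adipose tissue, and the median log2 excess of the adipocyte markers other than Car3 was 4.20. The atrial markers other than Myl4, Myl7 and Sln had a median excess of 0.625, with Nppa at 326 against 70.7 CPM and a WT mean of 175 (lower in TG within the deeper libraries, log2 fold change -1.44, edgeR with Benjamini-Hochberg adjusted p = 5.84e-05) and the abundant Clu at 992 against 930, and those of skeletal muscle (0.84, 10 of 12 higher, several near the floor) and of pulmonary vein or conduction tissue (0.79, 7 of 9 higher) stood about as high, so more atrium or more of another of these tissues is a further hypothesis. In the other TG libraries, where Carns1 lay between 19094 and 24288 CPM against 19071 in replicate 2, the same adipocyte markers had a median log2 excess over the WT mean of -0.10, -0.22 and 0.49, against 4.41 in replicate 2, which argues against the transgene as the whole cause of their level there.

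The separation of the 4 deeper from the 4 shallower libraries was weighed against GC content, read number and genotype. Thinning every library to 6261193 counts gave 3852 genes past the threshold, of which 3724 were among the 4078 found without thinning. Thinning keeps the make-up of each library, and the fit already scales by library totals. Most calls therefore had to remain, and this test cannot decide whether the number of reads is the cause. The deeper class holds 2 TG libraries, which argues against genotype. Offsets for GC content and gene length gave 870 genes, 618 of them among the 4078. The fold change between the classes had a Spearman rho of -0.69 with GC content and 0.29 with length. A step of library making or sequencing that depends on GC content or length may account for most of the separation. The offsets removed both trends together, so their parts cannot be told apart. The labels give no batch or date, and no biological explanation of the classes was tested.

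The lower immediate early genes in TG were weighed against the classes of libraries, GC content and the choice of samples. Each class holds 2 libraries of each group, and within the deeper class the median of the list was -0.53 and camera called it (adjusted p = 0.903 with an estimated correlation), which argues against a shift between the classes as the whole cause, while within the shallower class the median was -0.11 and the list was not called (Benjamini-Hochberg adjusted p = 0.119). With GC and length offsets the median was -0.25 and the list was still called (adjusted p = 0.669 with an estimated correlation, 0.835 without the offsets, where fry gave 0.902), which argues against a trend with GC content or length as the whole cause. Of the 35 splits of the 8 libraries into groups of 4, 4 gave this list a camera p as small as the real 7.87e-11, and the smallest of the others was 5.53e-23, so chance cannot be excluded. These genes respond within minutes to handling of the tissue, and such handling, like an effect of the transgene, remains an open and untested explanation.

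The counts of calls were set against the same splits. For the 2 genes, 4 of 35 splits gave as many, so chance cannot be excluded for the count, and the highest of the others, 3803 genes, was the split of deeper from shallower libraries fitted without the group, where the fit with the group gave 4078, which points to that structure of the samples. For the 9 lists, 19 of 35 splits gave as many, with up to 18 in the others, so chance cannot be excluded. With the class as a covariate the real split gave 28 genes, and the highest of the other splits with 2 libraries of each class per group gave 2 genes. These 18 splits, of which 1 reached 28, are too few for a share under 0.05.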

How the results depend on the processing

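Fits named here with the depth class, GC and length offsets, 1 class alone, Carns1 left out or a shortened list were chosen after seeing the data. The log2 fold change of Carns1 lay between 8.24 and 8.46 and past the threshold in every fit that kept its counts. The counts of genes, given as changed, higher and lower in TG against 2, 1 and 1, were 15, 6 and 9 with DESeq2, 4, 2 and 2 with no low-count filter, and 1, 1 and 0 with limma on log2(FPKM + 1) and on log2(FPKM + 0.1). They were 28, 10 and 18 with the depth class as a covariate, 5, 2 and 3 with GC and length offsets, 59, 17 and 42 in the deeper libraries only, 4, 3 and 1 in the shallower libraries only, and 0, 0 and 0 with Carns1 reads left out, where 441 genes had an unadjusted p under 0.05, again a smaller share than chance gives. Lrrc15 was not past the threshold in that last fit (edgeR, Benjamini-Hochberg adjusted p = 0.070), at a log2 fold change of -1.32 (SE 0.18). Genes with an unadjusted p under 0.05 numbered 1136 with the depth class as a covariate and 777 with GC and length offsets. Both are larger shares than chance gives. Leaving out 1 library gave 1 to 3 genes changed, 1 to 2 higher and 0 to 2 lower. RLE and upper-quartile scaling, a mean of at least 5 CPM and voom with library weights gave 2, 1 and 1. A fit with sex as a covariate was not run, since every library showed the male pattern.

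With the replicate number as a block (replicate block) 1 gene changed, 1 higher and 0 lower, and 11 lists were called. Samples sharing a number had correlations of 0.32, -0.38, -0.24 and 0.48 in their deviations from the group means, and not every sample correlated best with its own number, so the numbers were not taken to pair samples.

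The number of lists called, 9, was 1 with camera and an estimated correlation, 1 with fry, 1 with the depth class and an estimated correlation, 5 with GC and length offsets, and between 6 and 12 otherwise, with 7 to 12 when 1 library was left out. Reversed directions, by camera, were found in 7 lists. The histidyl dipeptide list had a median of -0.0127 with Carns1 reads left out and -0.0149 without Carns1 as a member, which shows that Carns1 carried it. Nuclear oxidative phosphorylation had medians between -0.128 and 0.0065 when 1 library was left out, the highest without WT replicate 2, and adipocyte markers between -0.0120 and 0.639, the lowest without TG replicate 2. In the deeper libraries only, the medians were -0.0140 for cardiac stress, -0.335 for atrial markers and -0.0391 for the unfolded protein response, and in the shallower only, 0.20 for erythroid markers. Except for the Carns1 member, the cause was not tested.

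Of 1948 values of 90 named genes under the alternatives, 1870 kept their side of the threshold, 11 lost and 67 gained a call, and none reversed; 45 values below the threshold changed sign. Of 900 values of 36 lists, 795 kept their side, 64 lost and 33 gained a call, and 59 not called changed sign. The median of all genes moved by less than 0.1 on the log2 scale in every fit. At this depth and number of samples, with the design of group alone, a 1.5-fold change was found in 30.7% of simulated cases, so changes of that size can be missed. Differences between the depth classes entered the simulated counts as noise between libraries. Recovery with the class as a covariate was not simulated. The simulated runs held 200 changed genes each. With fewer changed genes the Benjamini-Hochberg threshold is stricter, so recovery here may be lower than simulated.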

Other observations

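The fit and the genes in this part were chosen after the data were seen. With the depth class of the libraries as a covariate, 28 genes passed the threshold in edgeR with Benjamini-Hochberg adjustment. Irs2, an adaptor of the insulin receptor, stood at 8.62 ± 1.10 CPM in TG and 27.9 ± 18.3 in WT, with 46.5 and 40.7 CPM in the deeper and 13.5 and 11 in the shallower WT libraries. Ogdhl had a log2 fold change of -0.88 (SE 0.11), Cox7a1 -0.46 (SE 0.08) and Tecr, an enzyme of very long chain fatty acid synthesis, -0.45 (SE 0.07) in that fit. Dio2, which activates thyroid hormone, stood higher in TG with a log2 fold change of 1.70 (SE 0.30), with 7.77 and 4.75 CPM in TG replicates 2 and 4, 1.57 and 1.25 in TG replicates 1 and 3 and at most 1.99 in WT. It is known from brown fat, and in TG replicate 2 the brown fat gene Ucp1 stood at 124 CPM against a mean of 0.17 in the other TG libraries, with 0 in TG replicate 4.

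The transcription factor genes Jun (-0.69, SE 0.09) and Fosl2 (-0.98, SE 0.14) were lower in TG in the same fit. So were the calcium-binding protein Tesc (-0.66, SE 0.09), the muscle ubiquitin ligase adaptor Asb14 (-0.58, SE 0.08), the lipoxygenase Alox5 (-0.63, SE 0.11), the oxygenase Phyhd1 (-0.70, SE 0.12), the nucleoside diphosphate kinase Nme4 (-0.94, SE 0.17), Smim3 (-0.71, SE 0.12), Lgi1 (-1.16, SE 0.21) and the neurotrophic factor Nrtn (-0.57, SE 0.10). The chaperone genes Hsph1 (0.69, SE 0.12) and St13 (0.42, SE 0.07) were higher, beside Fam81a, Sort1, Cxcl9, Hyal1 and Tmem130. The groups overlapped in St13, Lgi1, Nrtn, Hsph1 and Dio2. Each of the genes named in this part, except Ucp1, which did not pass the filter on counts, had a Benjamini-Hochberg adjusted p above 0.05 in the main edgeR fit, which lacks the covariate.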
